A study of Mus musculus with 29 samples.

How the data were processed

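Per the labels' protocols, common bile ducts were microdissected, digested with dispase, pronase and collagenase, and sorted by flow cytometry, with about 1000 mesenchymal cells per animal going straight into lysis buffer. Full-length cDNA was made by a Smart-seq3-type protocol with oligonucleotides of Smart-seq2, and libraries with an enzymatic fragmentation kit (New England Biolabs Ultra II FS). The authors deposited raw read counts per gene, as whole numbers, in 1 table for the Gli1 libraries and 1 table per Pdgfra genotype. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the gene annotation and the use of strand are not given in the sources used here. The counts carry no molecular identifiers, so reads copied by PCR count separately, and amplification from few cells can raise the spread of weakly expressed genes. Reads from near-identical copies such as pseudogenes of ribosomal protein genes, and from overlapping or antisense genes, can be split between them in ways that depend on the aligner, and values of such genes are uncertain.

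All tables held the same 55401 gene symbols, with 55291 distinct ones, of which 53292 were found in GENCODE M21. The 110 symbols that repeat another were kept as separate entries. Every column was matched to its sample by the sample's title. Groups and replicate numbers come from the titles, giving 6 Gli1 and 23 Pdgfra libraries in 9 groups. The description of wild type replicate 5 also names the SmoFF allele, unlike its title and genotype label, and it was kept as wild type. No pair of libraries of one group held identical counts, and each pair differed by far more than sampling noise. Total counts were 15021796 to 38301189 per library, of which 2.37 to 50.03% lay on the ribosomal RNA locus CT010467.1. That locus was kept in the library sizes. At these depths the number of animals and the small cell input limit precision more than counting error does.

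Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest with default settings), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The Gli1 libraries were fitted alone, and all 23 Pdgfra libraries in a single fit that shares the estimate of spread, with contrasts for each genotype against wild type, SmoM2 against SmoFF and Gli2FFGli3FF against SmoFF. A further contrast tested the departure of Gli2FFGli3FF from the sum of the Gli2FF and Gli3FF changes. The tests estimate log2 fold changes with standard errors, taken from the fit. The 35 gene lists cover pathways, matrix and contractile genes, stress responses and markers of cell types that the sort could let through. Each list with at least 3 tested genes was tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists of one comparison.

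Genes named in the text follow a rule. It takes the targeted genes and genes of the Hedgehog pathway, among them Smo, Gli1, Gli2, Gli3, Ptch1 and Hhip. It then takes up to 8 called genes with the largest rise and 8 with the largest fall among those with a mean log2 CPM of at least 3, every library of one group beyond every library of the other, and a symbol that is no clone, predicted gene or pseudogene name. Last come, per list, up to 4 called members with the smallest p. The text may leave members out. The groups, tests, gene lists, naming rule and the first set of other settings were fixed before the data were examined.

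The other settings of that first set were RLE and upper quartile scaling, DESeq2 1.42.0, limma voom with sample quality weights, no filter on low counts, a filter at 10 counts, the replicate number as a block, a fit of only the groups compared, removal of sex-linked transcripts, and leaving out each library in turn. Settings chosen after seeing the data were wild type 1 to 3 or 4 and 5 as the only controls, a correction for GC content and transcript length, the ribosomal RNA share as a covariate, protein-coding genes outside the ribosomal proteins only, libraries with Xist under 5 CPM of total counts only, and a count without cell cycle genes. The pseudogene measure that parts the wild type libraries was also defined after seeing the data, as pseudogenes with a log2 difference over 2 between the sets (prior count 0.5).

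The tests were tried on simulated data with 100 genes changed 2-fold and 100 changed 4-fold, drawn from the means, dispersions and library sizes of the real libraries. In the simulated SmoFF comparison (21506 genes) 14% of the 2-fold and 44% of the 4-fold changes were recovered with 0 false calls, and in the simulated SmoM2 comparison (21473 genes) 11% and 42% with 2 false calls. In the simulated ligation comparison (15090 genes) 0% and 16% were recovered with 0 false calls, and in that of Gli2FF (21537 genes) 2% and 24% with 2 false calls. Changes of these sizes in a typical gene were thus often missed in these simulations. They changed few genes, which makes the adjusted threshold stricter than where many genes are called, as after ligation (2326 of 17150). The recovered shares may therefore understate what such a comparison can show. Up to 100 splits of the libraries were tested per comparison with at least 3 libraries in each group, and this number was raised after a smaller draw had been seen.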

Results

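RNA-seq was done on mesenchymal cells sorted from around the common bile duct of mice, about 1000 cells per animal, in 29 libraries of 9 groups. Gli1-CreERT2 tdTomato mice, whose label marks cells with active Gli1 and their descendants, gave 3 uninjured libraries and 3 libraries taken on day 4 after bile duct ligation (BDL). Pdgfra-CreERT2 tdTomato mice, whose label marks Pdgfra-expressing fibroblasts, gave 5 wild type libraries, 4 SmoFF, 3 SmoM2, 3 Ctnnb1FF, 2 Gli2FF, 2 Gli3FF and 4 Gli2FFGli3FF libraries. FF is read here, by the convention of mouse genetics, as homozygous loxP-flanked alleles that Cre removes, and SmoM2 as a constitutively active form of Smo. Total counts per library lay between 15021796 and 38301189, the lowest and highest being Gli2FF replicate 1 and Gli2FFGli3FF replicate 2. The labels' protocol takes each library from an individual animal, so p-values measure the spread between these animals and their libraries. In Gli2FFGli3FF, transcripts of both sexes occur within a library (values below), which leaves open whether each library there holds a single animal. Values are library-size scaled counts (CPM) as mean ± SD over the libraries of a group, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Where log2 changes are given relative to a median over all genes, calls, counts of called genes and adjusted p-values are those of the unshifted changes.

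The libraries differed in measures of RNA makeup that moved with the groups. The ribosomal RNA locus CT010467.1 took 20.6 ± 6.06% of counts in wild type (n = 5), 18.8 ± 9.26% in SmoFF (n = 4), 17.3 ± 5.32% in SmoM2 (n = 3) and 11.03 ± 3.49% in Gli2FF (n = 2). In Ctnnb1FF, Gli3FF and Gli2FFGli3FF it took 30.7 ± 3.29% (n = 3), 31.8 ± 10.3% (n = 2) and 44.6 ± 5.89% (n = 4), against 2.87 to 3.37% in the means of the Gli1 groups. Ctnnb1FF libraries held 15892 to 17726 detected genes and Gli2FFGli3FF libraries 17508 to 20055, against 21127 to 24483 in wild type. The wild type libraries fell into a pair of sets. Replicates 1 to 3 lay above replicates 4 and 5 by the fixed margin for 1055 of 3461 tested pseudogenes, and 193 genes of that kind lay lower. A test of the sets against each other called 428 genes, of which 340 were pseudogenes, 328 of them higher in replicates 1 to 3. The median of those 1055 pseudogenes was 0.53 to 0.81 log2 CPM in wild type 1 to 3 and 0.03 to 0.51 in SmoM2. It was −2.926 and −2.999 in wild type 4 and 5 and between −3.28 and −1.35 in the libraries of the other Pdgfra genotypes. By this measure SmoM2 lies near wild type 1 to 3 and SmoFF near wild type 4 and 5. The labels name neither a batch nor a strain for these sets, and the cause of the split was not tested.

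**Figure D1:**
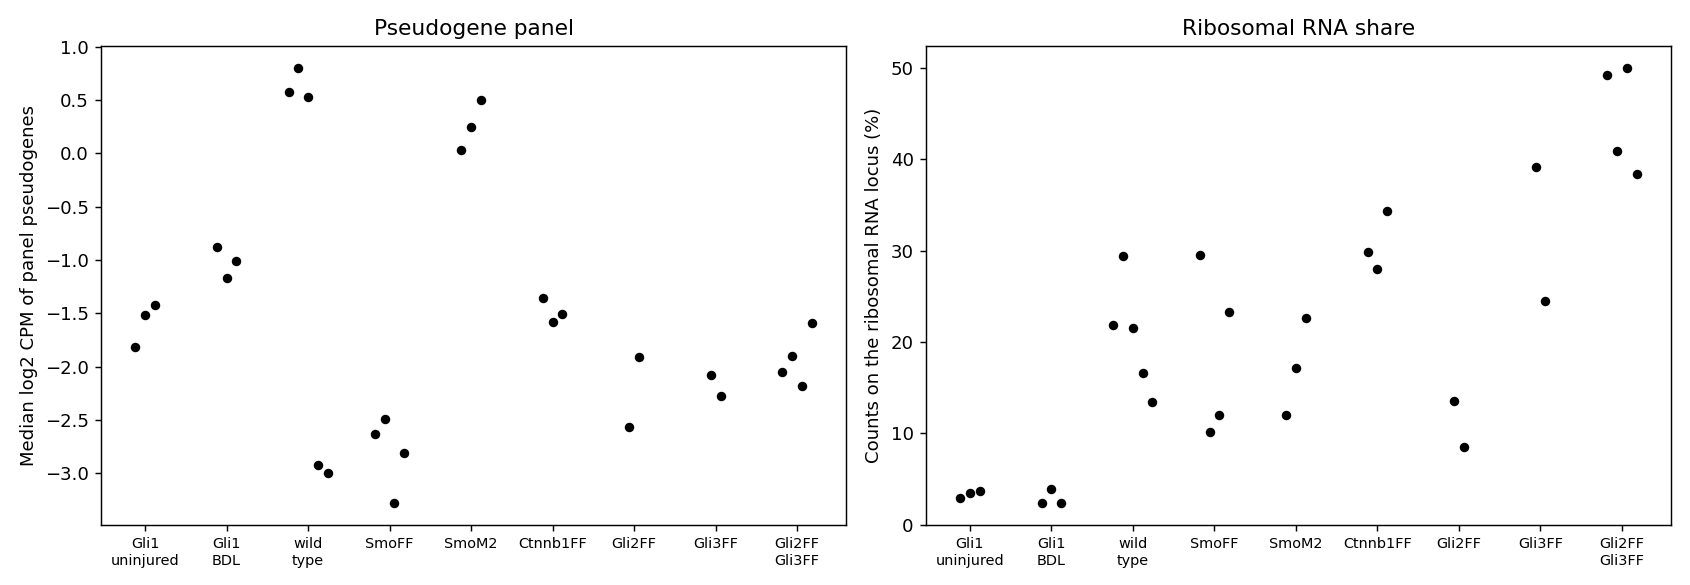
Each point is 1 library: one panel gives the median log2 CPM of the pseudogenes that part wild type replicates 1 to 3 from 4 and 5, the other the percent of counts in the ribosomal RNA locus, by group. Wild type replicates 1 to 3 and SmoM2 lie above 0 in the first measure and all other libraries below it. The Gli2FFGli3FF libraries, at 38.4 to 50.03%, have the highest mean ribosomal RNA share.

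The Hedgehog pathway genes and Ctnnb1 are given in mm10 coordinates from the GENCODE M21 annotation, in which each is a protein-coding gene. Smo, the transmembrane transducer of the pathway, lies on chromosome 6 from 29735503 to 29761365. The transcription factors Gli1, Gli2 and Gli3 lie on chromosome 10 from 127329882 to 127341974, chromosome 1 from 118834132 to 119053619 and chromosome 13 from 15463235 to 15730026. Ptch1 and Hhip, which bind Hedgehog ligand and are themselves target genes, lie on chromosome 13 from 63508328 to 63573598 and chromosome 8 from 79965851 to 80058006. Ctnnb1, which encodes beta-catenin, lies on chromosome 9 from 120929216 to 120960507. The labels do not say which exons are flanked in the FF alleles, and reads from the rest of each transcript stay in its count.

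BDL was compared with uninjured ducts to ask what differs in Gli1-lineage cells after ligation. The labels name no sham-operated group, so effects of the surgery cannot be separated from those of obstruction. Myl9, a myosin light chain of smooth muscle, was at 935 ± 32.5 CPM after ligation against 86.0 ± 3.74 (n = 3 each). The collagen gene Col1a1 was at 35780 ± 5245 against 3681 ± 469 and the collagen crosslinking enzyme Lox at 1285 ± 126 against 122.5 ± 10.6. Lower after ligation were the small proteoglycan Dcn, at 3619 ± 206 against 21230 ± 1922, and the actin-severing protein Gsn, at 415 ± 88.9 against 21480 ± 2925. The median over all genes was 0.069 log2, against 0.032 with RLE scaling in edgeR, and lay 0.269 higher with DESeq2. Log2 changes of genes and lists in this comparison are given relative to the 0.069.

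Of 22 myofibroblast and contractile genes tested, 16 were higher and 2 lower (19 and 2 adjusted over the list alone), with a median of 3.19. Myl9 rose by 3.37 (SE 0.14), Tpm2 by 3.43 (SE 0.16) and Timp1, a protease inhibitor, by 3.62 (SE 0.19), each with adjusted p = 0.000508. Actg2, the enteric smooth muscle actin, was at 727 ± 87.4 CPM after ligation, with 1 count over the 3 uninjured libraries. Limma's camera gave the list adjusted p = 1.52e-10, or adjusted p = 0.0575 with an estimated correlation. Smooth muscle and pericyte markers went 7 higher and 0 lower of 16 (10 and 0 adjusted over the list alone; camera adjusted p = 2.68e-05, and adjusted p = 0.0926 with an estimated correlation), with Myh11 at 171 ± 60.2 against 0.921 ± 0.786 CPM. Fibrillar matrix genes went 19 higher and 6 lower of 39 (21 and 6 adjusted over the list alone; camera adjusted p = 0.00602, and adjusted p = 0.539 with an estimated correlation). Col12a1 rose by 4.68 (SE 0.27) and Dcn fell by 2.62 (SE 0.15). Cell cycle genes went 14 higher and 0 lower of 44 (29 and 0 adjusted over the list alone), with camera adjusted p = 8.32e-11 and adjusted p = 0.363 with an estimated correlation. Genes of oxidative phosphorylation went 11 higher and 0 lower of 38 (15 and 0 adjusted over the list alone; camera adjusted p = 0.00532, and adjusted p = 0.554 with an estimated correlation), among them cytochrome c, Cycs, which rose by 1.55 (SE 0.18). The insulin-like growth factor binding protein Igfbp2 was at 1437 ± 571 against 2.37 ± 1.96 CPM and the monocyte chemokine Ccl2 at 146 ± 39.0 against 8.70 ± 5.26.

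Of 18 complement genes 2 were higher and 12 lower (2 and 13 adjusted over the list alone; camera adjusted p = 1.21e-08, and adjusted p = 0.0873 with an estimated correlation). C3 was at 533 ± 82.4 CPM after ligation against 4852 ± 689, while Cd59a, an inhibitor of the membrane attack complex, rose by 3.67 (SE 0.26). Interferon response genes went 0 higher and 15 lower of 32 (0 and 23 adjusted over the list alone), with camera adjusted p = 1.84e-14 and adjusted p = 0.174 with an estimated correlation. Iigp1 fell by 4.17 (SE 0.42) and Oasl2 by 3.04 (SE 0.31). MHC class II genes went 0 higher and 3 lower of 6 (0 and 5 adjusted over the list alone; camera adjusted p = 0.000123, and adjusted p = 0.186 with an estimated correlation), H2-Ab1 being at 1.85 ± 0.651 against 52.3 ± 6.71 CPM. Fibroblast identity genes went 4 higher and 14 lower of 25 (5 and 17 adjusted over the list alone; camera adjusted p = 1.35e-07, and adjusted p = 0.174 with an estimated correlation). Clec3b and Dpp4, markers of adventitial fibroblasts, fell by 7.22 (SE 0.77) and 6.12 (SE 0.74). Markers of other cells moved as well. Mesothelial markers went 0 higher and 10 lower of 12 (0 and 11 adjusted over the list alone; camera adjusted p = 1.21e-08, and adjusted p = 0.174 with an estimated correlation), while 3 of 15 immune markers were higher. Endothelial markers went 3 higher and 1 lower of 12, also adjusted over the list alone (camera adjusted p = 0.492, fry adjusted p = 0.00168). Cholangiocyte markers went 0 higher and 0 lower of 16 by edgeR (0 and 4 at unadjusted p < 0.05, 0 and 3 by DESeq2, 1 and 0 by limma voom). Immediate-early genes, which also respond to tissue dissociation, went 4 higher and 15 lower of 34 (4 and 17 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.174 with an estimated correlation), with Fos at 296 ± 14.4 against 2286 ± 223 CPM.

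Gli1, Ptch1 and Hhip did not pass the threshold after ligation. Gli1 was at 11.8 ± 1.47 against 16.6 ± 12.03 CPM (adjusted p = 0.673), Ptch1 at 56.2 ± 21.7 against 53.6 ± 7.60 (adjusted p = 0.929) and Hhip at 7.43 ± 5.73 against 11.2 ± 5.04 (adjusted p = 0.74). Of 13 Hedgehog target genes 1 was higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.856). Osr1, among the lower, was at 50.02 ± 29.4 against 334 ± 64.5 CPM (adjusted p = 0.0154) and was not called without BDL replicate 3 (adjusted p = 0.0954). Hedgehog receptors and transducers went 2 higher and 2 lower of 20, also adjusted over the list alone (camera adjusted p = 0.289). Of 17150 genes tested, 1332 were higher and 994 lower, 2326 in all. The count was 1482 without uninjured replicate 2, 882 without BDL replicate 1, 420 without BDL replicate 2 and 377 without BDL replicate 3.

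**Figure D2:**
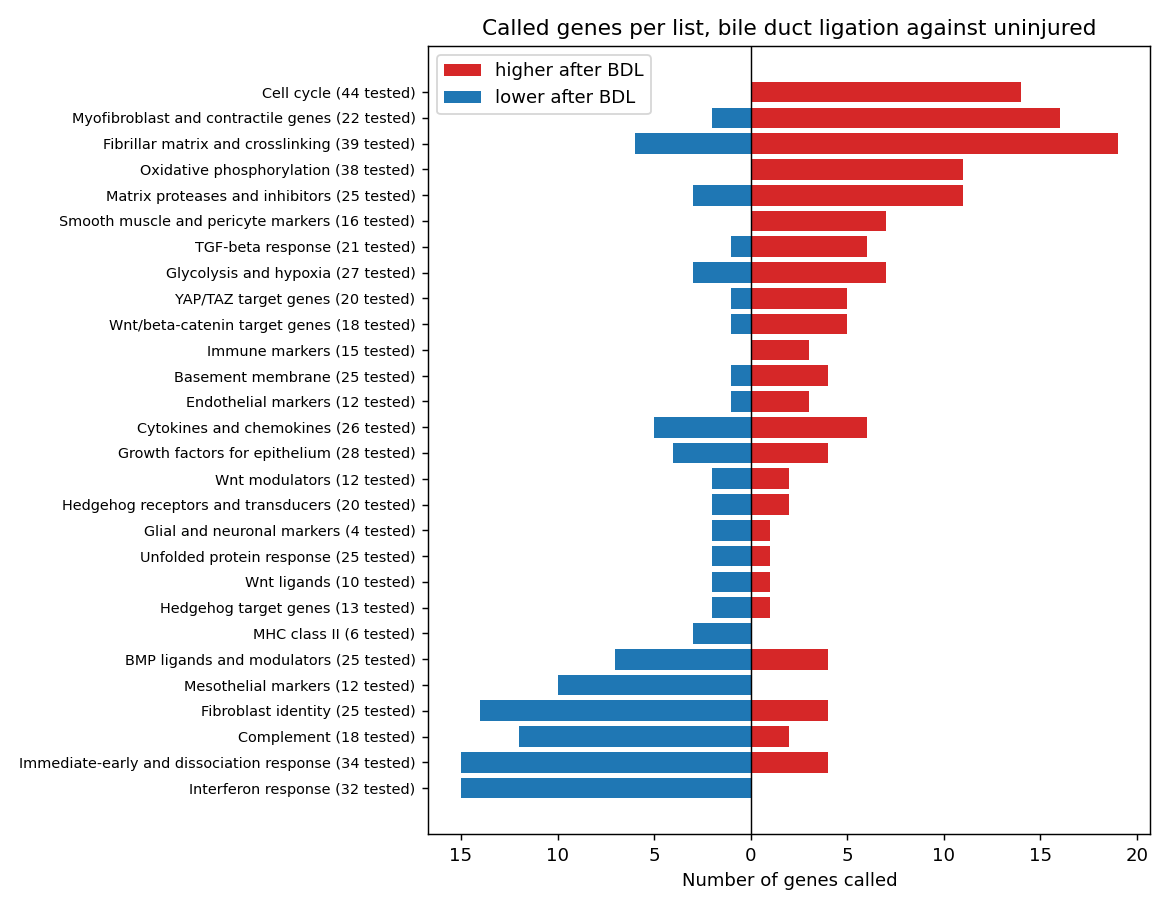
Bars give, for each gene list with at least 3 called genes, how many members were called higher (right of 0) or lower (left of 0) on day 4 after ligation against uninjured ducts, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Myofibroblast genes (16 higher, 2 lower) and fibrillar matrix genes (19 higher, 6 lower) lie mostly to the right, and interferon response genes (0 higher, 15 lower) to the left.

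SmoFF was compared with wild type to ask what loss of Smo changes. Smo was at 9.05, 7.79, 6.81 and 7.86 CPM in SmoFF replicates 1 to 4 and at 36.3, 25.5, 22.6, 35.2 and 28.7 in wild type replicates 1 to 5. It fell by 1.91 log2 (SE 0.22, adjusted p = 3.06e-05). The fibrillar collagen gene Col1a1 was at 1462 ± 470 CPM against 3909 ± 732 and fell by 1.42 (SE 0.18, adjusted p = 0.000162). Ucp2, an uncoupling protein of mitochondria, was at 177 ± 56.5 against 22.3 ± 2.82 and rose by 2.98 (SE 0.27, adjusted p = 7.88e-07). The Hedgehog target genes went 0 higher and 0 lower of 13 by edgeR, also adjusted over the list alone (1 and 1 at unadjusted p < 0.05, 0 and 0 by DESeq2 and by limma voom; camera adjusted p = 0.618). Gli1 was at 12.04 ± 5.98 against 13.8 ± 7.72 CPM, Ptch1 at 29.8 ± 4.44 against 30.8 ± 6.55 and Hhip at 1.39 ± 1.01 against 5.66 ± 5.54 (adjusted p = 0.957, 0.992 and 0.168).

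Of 39 fibrillar matrix genes 9 were lower and 0 higher (0 higher and 22 lower adjusted over the list alone), with camera adjusted p = 6.44e-15 and adjusted p = 0.0872 with an estimated correlation. Col3a1 was at 2878 ± 905 against 6340 ± 1791 CPM and the proteoglycan Bgn at 1210 ± 221 against 2451 ± 347. The basement membrane collagen Col4a5 fell by 1.30 (SE 0.20), Pdgfrl by 2.09 (SE 0.30) and the adhesion protein Fbln7 by 3.04 (SE 0.41). The Wnt ligand gene Wnt4 rose by 2.43 (SE 0.38) and the BMP target Id1 by 2.18 (SE 0.40). Immediate-early genes went 1 higher and 0 lower of 34 (7 and 0 adjusted over the list alone; camera adjusted p = 3.36e-07, and adjusted p = 0.334 with an estimated correlation). Mesothelial markers went 0 higher and 0 lower of 12 by edgeR (9 higher adjusted over the list alone, 9 and 0 at unadjusted p < 0.05, 4 and 0 by DESeq2, 2 and 0 by limma voom; camera adjusted p = 1.05e-05, and adjusted p = 0.334 with an estimated correlation) and pancreatic acinar markers 0 and 0 of 14 (3 higher adjusted over the list alone, 5 and 0 at unadjusted p < 0.05, 2 and 0 by DESeq2, 1 and 0 by limma voom; camera adjusted p = 0.00763, and adjusted p = 0.0872 with an estimated correlation).

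Of 24383 genes tested, 70 were higher and 307 lower in SmoFF, and 185 of the lower ones were pseudogenes. Xist was under 5 CPM of total counts in 2 of 4 SmoFF libraries and in all 5 of wild type, so differences tied to sex may enter. With low-Xist libraries only, which are fewer, 7 of 25 named calls were lost. With the nearer wild type 4 and 5 as controls the comparison called 19 genes, 18 of them among the 377, and against wild type 1 to 3 it called 1122. Against wild type 4 and 5 Smo changed by −2.02 (adjusted p = 0.00108), Col1a1 by −1.20 (adjusted p = 0.0354), Fbln7 by −2.91 (adjusted p = 0.0223), Pdgfrl by −2.07 (adjusted p = 0.0492) and Ucp2 by 2.97 (adjusted p = 0.0044). Col3a1 (−0.86), Bgn (−0.785), Col4a5 (−1.13), Wnt4 (2.32) and Id1 (2.64) kept their direction but were not called there. The count was 160, 166, 166, 618 and 685 without wild type replicate 1, 2, 3, 4 or 5 and 200, 176, 121 and 123 without SmoFF replicate 1, 2, 3 or 4.

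SmoM2 was compared with wild type to ask what Smo activity beyond the normal level changes. The Hedgehog feedback genes Ptch1 and Hhip rose. Ptch1 was at 274, 385 and 248 CPM in SmoM2 replicates 1 to 3 against 30.8 ± 6.55 (log2 change 3.29, SE 0.35, adjusted p = 6.15e-05), and Hhip at 197, 284 and 183 against 5.66 ± 5.54 (log2 change 5.29, SE 0.75, adjusted p = 0.000873). Smo itself was at 49.4, 52.8 and 37.5 CPM (adjusted p = 0.373) and Gli1 at 40.2 ± 19.7 against 13.8 ± 7.72 (adjusted p = 0.535). Hp, which encodes the acute-phase protein haptoglobin, fell by 3.42 (SE 0.46), the vasodilator peptide gene Adm by 2.10 (SE 0.29) and the interferon-induced Ifi211 by 1.45 (SE 0.21). The imprinted gene Mest rose by 2.40 (SE 0.34). Hedgehog target genes went 3 higher, Ptch1 and Hhip among them, and 1 lower (Osr1) of 13 (5 and 1 adjusted over the list alone), with camera adjusted p = 0.000121 and adjusted p = 0.0206 with an estimated correlation. The transcription factor Osr1 was at 87.2 ± 9.99 against 202 ± 29.5 CPM. Its fall was not particular to SmoM2. Osr1 was also called lower against wild type in Gli2FF (log2 change −1.328), Gli3FF (−1.825) and Gli2FFGli3FF (−1.218, not relative to all genes). In SmoFF it was at 185 ± 9.17 CPM. Osr1 was not called without SmoM2 replicate 1 (−1.19, adjusted p = 0.0724) or 2 (−1.18, adjusted p = 0.0903).

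In SmoM2 myofibroblast and contractile genes went 3 higher and 0 lower of 22 (10 and 0 adjusted over the list alone; camera adjusted p = 3.99e-05, and adjusted p = 0.0177 with an estimated correlation), the smooth muscle actin Acta2 being at 185 ± 14.0 against 30.3 ± 2.88 CPM. Acta2 was not called when any of the 8 libraries was left out (log2 change from 2.55 to 2.64, adjusted p from 0.0811 to 0.148). Smooth muscle and pericyte markers went 0 higher and 0 lower of 17 by edgeR (4 and 0 adjusted over the list alone, 6 and 0 at unadjusted p < 0.05, 0 and 0 by DESeq2, 5 and 0 by limma voom; camera adjusted p = 0.000121, and adjusted p = 0.0184 with an estimated correlation). Wnt/beta-catenin target genes went 1 higher and 0 lower of 21 (10 and 0 adjusted over the list alone; camera adjusted p = 8.82e-05, and adjusted p = 0.0177 with an estimated correlation). Pancreatic acinar markers, of a neighbouring organ, went 0 higher and 0 lower of 14 by edgeR (2 and 0 adjusted over the list alone, 4 and 0 at unadjusted p < 0.05, 0 and 0 by DESeq2, 4 and 0 by limma voom; camera adjusted p = 9.48e-05, and adjusted p = 0.0124 with an estimated correlation). Fibrillar matrix genes went 1 higher and 0 lower of 39 (3 and 3 adjusted over the list alone; camera adjusted p = 0.381). The test called 31 genes higher and 19 lower of 24383, and DESeq2, with its own scaling, 120 and 159. Against wild type 1 to 3, the nearer set by pseudogene counts, 19 genes were called, among them Ptch1 (3.33, adjusted p = 0.00894), Hhip (5.69, adjusted p = 0.0117), Hp, Adm, Ifi211 and Osr1 but not Mest (2.23, adjusted p = 0.0504) or Acta2, and against wild type 4 and 5 186. The count was 25, 33, 28 and 30 without wild type replicate 1, 2, 3 or 4 and 17, 19 and 30 without SmoM2 replicate 1, 2 or 3.

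**Figure D3:**
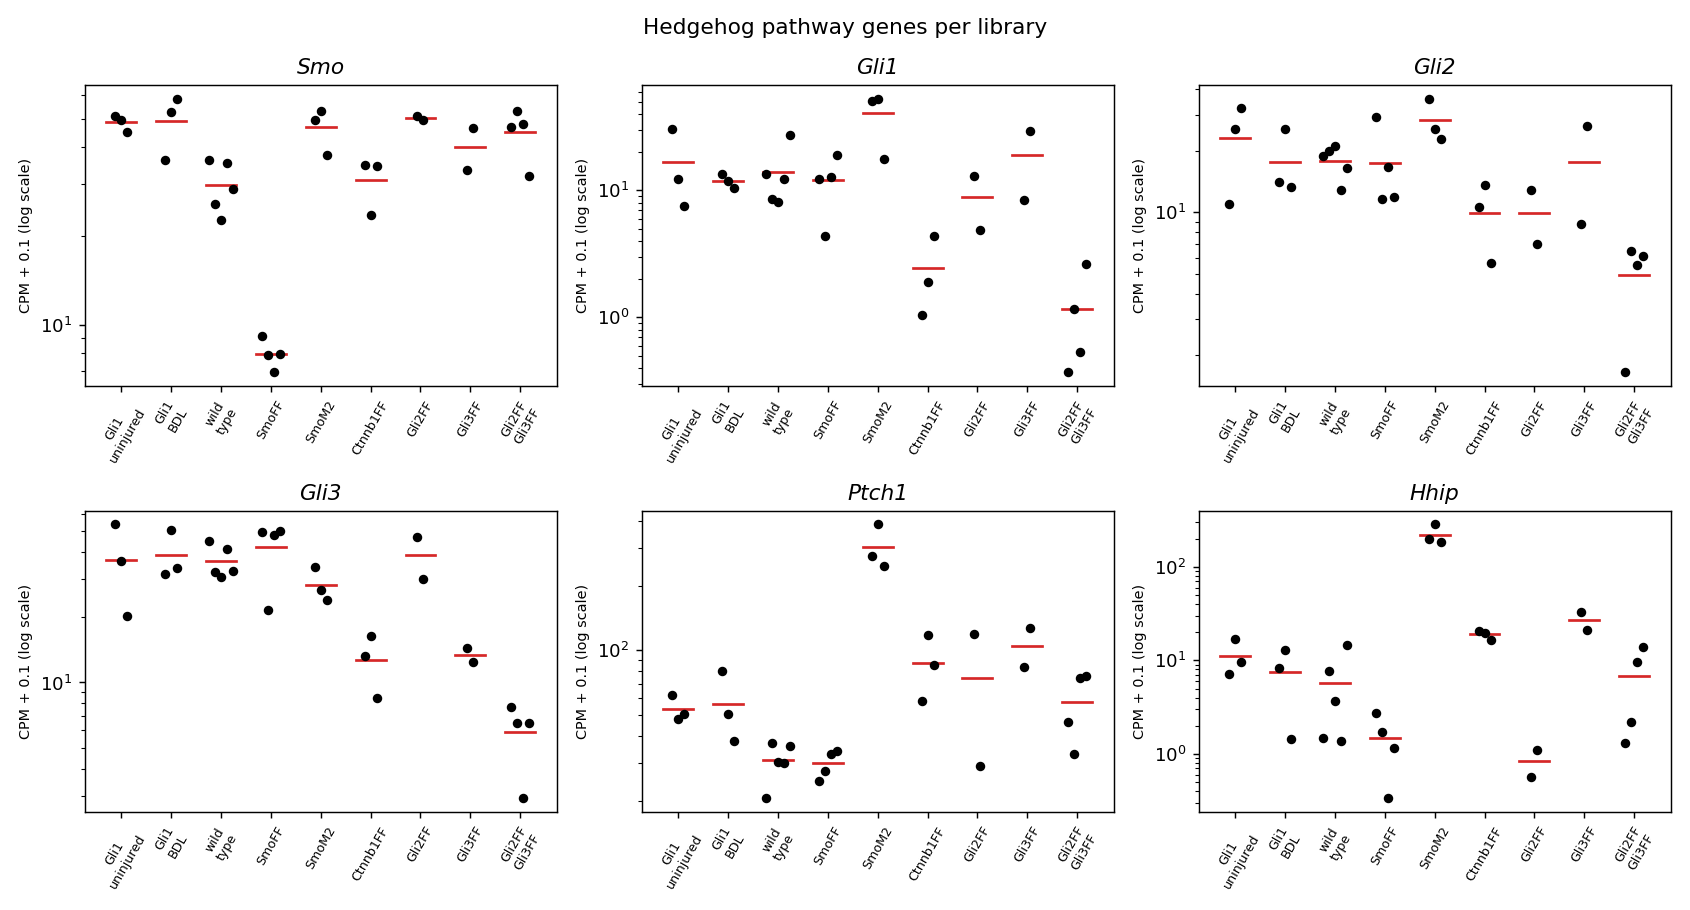
CPM (plus 0.1, log axis) of Smo, Gli1, Gli2, Gli3, Ptch1 and Hhip in each library (points) with the group mean (line), by group. Ptch1 and Hhip are highest in SmoM2, at 302 and 221 CPM on average, Smo is lowest in SmoFF (7.88 CPM), and Gli1 and Gli3 are lowest in Gli2FFGli3FF (1.07 and 5.81 CPM).

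SmoM2 was set directly against SmoFF, the activated against the deleted receptor. Smo differed by 2.56 log2 (SE 0.24), Ptch1 by 3.34 (SE 0.38), Hhip by 7.31 (SE 0.90) and Acta2 by 3.24 (SE 0.58, 185 ± 14.0 against 19.5 ± 21.1 CPM), all higher in SmoM2 (n = 3 against 4). The matricellular gene Ccn2 was at 23.3 ± 10.6 against 2.57 ± 1.33 CPM and the Wnt inhibitor Wif1 at 138 ± 39.7 against 11.3 ± 9.51. The activin inhibitor Fst (6.48 ± 0.471 against 76.1 ± 18.7) and the transcription factor Cebpb (3.41 ± 0.684 against 83.6 ± 3.99) were lower in SmoM2. Myofibroblast and contractile genes went 7 higher and 0 lower of 22 (9 and 0 adjusted over the list alone; camera adjusted p = 8.9e-06, and adjusted p = 0.0321 with an estimated correlation). Smooth muscle and pericyte markers went 1 higher (Lmod1) and 0 lower of 17, also adjusted over the list alone (camera adjusted p = 0.00555, and adjusted p = 0.152 with an estimated correlation). Cholangiocyte markers went 0 higher and 0 lower of 22 by edgeR, also adjusted over the list alone (0 and 6 at unadjusted p < 0.05, 0 and 1 by DESeq2, 0 and 0 by limma voom; camera adjusted p = 0.00968 toward lower, and adjusted p = 0.74 with an estimated correlation). Fibrillar matrix genes went 11 higher and 0 lower of 39 (18 and 1 adjusted over the list alone; camera adjusted p = 4.38e-07, and adjusted p = 0.305 with an estimated correlation). Hedgehog target genes went 3 higher and 1 lower of 13 (4 and 1 adjusted over the list alone; camera adjusted p = 0.0878). The test called 424 genes higher and 217 lower of 24383, 216 and 59 of them pseudogenes, and the groups lie on different sides of the pseudogene split, which cannot be separated from the genotypes here. The count was 361, 390, 311 and 367 without SmoFF replicate 1, 2, 3 or 4 and 269, 240 and 282 without SmoM2 replicate 1, 2 or 3.

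Ctnnb1FF was compared with wild type to ask what loss of beta-catenin changes. Ctnnb1 was at 47.9, 44.0 and 37.98 CPM in Ctnnb1FF replicates 1 to 3 and at 64.2, 58.2, 63.3, 53.8 and 53.2 in wild type replicates 1 to 5. Its log2 change of −0.44 (SE 0.19, adjusted p = 0.108) did not pass the threshold. The median over all genes was −0.612. It lay 0.050 higher with RLE scaling in edgeR, 0.156 higher with upper quartile scaling and 0.491 higher with DESeq2. Log2 changes in the rest of this comparison are relative to the −0.612. On that scale Ctnnb1 was at 0.18, above the median over all genes. The 15204 protein-coding genes outside the ribosomal proteins had a median of −0.35 before this shift, above Ctnnb1 at −0.44. Relative to those genes, rises in this comparison would be smaller and falls larger. The Wnt feedback genes Axin2 and Nkd2 fell by 2.02 (SE 0.57) and 1.03 (SE 0.41), Axin2 being at 4.78 ± 4.20 against 29.4 ± 6.81 CPM. Their log2 changes before the shift, which the calls test, were −2.634 and −1.647. Mgp, the matrix Gla protein, was at 4234 ± 1747 against 401 ± 86.4 and rose by 4.01 (SE 0.27). Wnt/beta-catenin target genes went 0 higher and 3 lower of 21 (Axin2, Nkd1 and Nkd2, also adjusted over the list alone), with a median of −0.48 (camera adjusted p = 0.378). Fry, which tests the unshifted changes of the list and not its place among other genes, gave adjusted p = 0.00114 toward lower. Nkd1 was not called without Ctnnb1FF replicate 3 (adjusted p = 0.0681).

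Of the Hedgehog genes Ptch1 was higher, at 86.9 ± 29.6 against 30.8 ± 6.55 CPM, and Gli3 lower, at 12.6 ± 3.97 against 36.4 ± 6.31. Gli1 was at 2.35 ± 1.74 against 13.8 ± 7.72, a call that was lost without Ctnnb1FF replicate 1 (adjusted p = 0.0794) or 2 (adjusted p = 0.0737). Growth factors for epithelium went 6 higher and 3 lower of 30 (7 and 5 adjusted over the list alone; camera adjusted p = 0.329). Kitl, Hgf and Fgf7, which act on epithelial or stem cells, rose by 3.13 (SE 0.36), 2.37 (SE 0.31) and 1.95 (SE 0.28). Of BMP ligands and modulators 6 of 25 were higher and 3 lower (7 and 3 adjusted over the list alone; camera adjusted p = 0.378), the BMP inhibitor Grem1 being at 80.1 ± 36.8 against 7.98 ± 4.35. The chemokine Ccl19 was at 135 ± 37.5 against 15.9 ± 0.718 and Cxcl12 at 2414 ± 411 against 1051 ± 154. Cytokines and chemokines went 7 higher and 3 lower of 33, also adjusted over the list alone (camera adjusted p = 0.245). Fibrillar matrix genes went 2 higher and 16 lower of 39 (3 and 21 adjusted over the list alone; camera adjusted p = 0.245), with a median of −0.01, level with all genes. Before the shift their median was −0.618, below the −0.35 of protein-coding genes outside the ribosomal proteins. The crosslinking enzyme Loxl1 fell by 1.56 (SE 0.26) and the secreted Wnt modulators Sfrp2 and Sfrp4 by 2.74 (SE 0.40) and 1.36 (SE 0.40). Oxidative phosphorylation genes went 30 higher and 2 lower of 38 (31 and 4 adjusted over the list alone), with a median of 1.98, camera adjusted p = 4.06e-21 and adjusted p = 0.701 with an estimated correlation. Cox6c, a subunit of cytochrome c oxidase, rose by 3.30 (SE 0.25). It moved with the library measures: mitochondrial transcripts took 10.1 to 11.6% of counts against 4.98 to 9.06% in wild type, and the structured RNA Rn7sk was at 2008 ± 639 against 34.2 ± 10.4 CPM.

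Ctnnb1FF libraries had Xist at 14.2 to 60.7 CPM, against a mean of 0.0446 in wild type, so differences tied to sex cannot be separated from those of the genotype in this comparison. The Y-linked Ddx3y was at 0.052 ± 0.0502 CPM, 3 counts over the 3 libraries, against 46.6 ± 10.5. Of the other cell types, mesothelial markers went 0 higher and 4 lower of 12 (0 and 5 adjusted over the list alone; camera adjusted p = 0.118). Of 24383 genes 1961 were higher and 2891 lower. The count was 3430 against wild type 1 to 3, 3450 against wild type 4 and 5, and 3050 without Ctnnb1FF replicate 2.

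Gli2FF was compared with wild type with 2 libraries against 5. Gli2 was at 12.8 and 6.91 CPM in Gli2FF replicates 1 and 2 and at 18.7, 19.7, 20.9, 12.8 and 16.5 in wild type replicates 1 to 5, a difference that did not pass the threshold (adjusted p = 0.398). The immediate-early gene Egr2 was at 74.0 ± 29.0 against 5.95 ± 2.42 CPM, Nr4a1 at 435 ± 89.8 against 51.2 ± 28.8 and the heat shock gene Hspa1b at 97.2 ± 0.880 against 13.2 ± 2.96. The list went 15 higher and 0 lower of 34 (20 and 1 adjusted over the list alone), with camera adjusted p = 2.72e-07 and adjusted p = 0.508 with an estimated correlation. The median over all genes was 0.116, against 0.210 with RLE scaling in edgeR and 0.000 with DESeq2. RLE scaling in edgeR thus did not bring it to the DESeq2 value. Whether the genes covered did so was not tested. Relative to the 0.116, Egr2 rose by 3.52 (SE 0.46), Nr4a1 by 2.97 (SE 0.42), Atf3 by 3.30 (SE 0.53) and the list's median was 0.96. Fibroblast identity genes went 1 higher and 8 lower of 25 (3 and 14 adjusted over the list alone; relative median −0.94; camera adjusted p = 2.4e-05, and adjusted p = 0.508 with an estimated correlation), and fibrillar matrix genes 1 higher and 8 lower of 39 (2 and 13 adjusted over the list alone; relative median −0.59; camera adjusted p = 0.000716, and adjusted p = 0.776 with an estimated correlation). Bgn was at 743 ± 46.8 against 2451 ± 347 CPM and Rps2, a ribosomal protein gene with near-identical pseudogenes, at 25.3 ± 0.924 against 490 ± 79.2. Ptch1 was at 120 and 28.9 CPM in the 2 libraries against 30.8 ± 6.55, and its call (adjusted p = 0.0484) was lost on leaving out any wild type library or Gli2FF replicate 1, without which the change was −0.12 (adjusted p = 1). The TMM scaling gave 628 genes higher and 795 lower of 24383, and RLE scaling 817 and 654. Of the TMM calls 21 higher and 234 lower were pseudogenes. The count was 200 against wild type 4 and 5, which like Gli2FF have low pseudogene counts, 1887 against wild type 1 to 3, and 895, 931, 179 and 588 without wild type 1, wild type 2, Gli2FF 1 or Gli2FF 2.

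Gli3FF was compared with wild type, again with 2 libraries. Gli3 was at 14.4 and 12.3 CPM in Gli3FF replicates 1 and 2 and at 44.9, 32.5, 30.8, 41.4 and 32.7 in wild type, a log2 change of −1.45 (SE 0.39, adjusted p = 0.0317) that was not called without wild type 1 (−1.36, adjusted p = 0.0659), Gli3FF 1 (−1.56, adjusted p = 0.223) or Gli3FF 2 (−1.34, adjusted p = 0.213). The Wnt inhibitor Wif1 was at 441 ± 1.71 against 24.4 ± 6.12 CPM, Bmp4 at 251 ± 29.6 against 30.1 ± 4.30, Sfrp2 at 1.07 ± 0.221 against 183 ± 49.0, Dpp4 at 1.17 ± 1.66 against 86.4 ± 20.2 and Pi16 at 73.4 ± 5.78 against 1179 ± 168. Over all genes the median was −0.220 (−0.069 over protein-coding genes outside the ribosomal proteins) and lay 0.179 higher with DESeq2. Relative to it Wif1 rose by 4.39 (SE 0.64) and Bmp4 by 3.28 (SE 0.30).

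Wnt/beta-catenin target genes went 5 higher and 0 lower of 21 in Gli3FF (7 and 0 adjusted over the list alone), with a relative median of 1.06, camera adjusted p = 2.44e-05 and adjusted p = 0.034 with an estimated correlation. The 5 were Wif1, Apcdd1, Tnfrsf19, Bambi and Myc, among which Wif1, Apcdd1 and Bambi encode inhibitors of Wnt, BMP or related signals (Tnfrsf19 and Bambi were chosen after their values were seen). Myc was not called without Gli3FF replicate 1 (1.38, adjusted p = 0.0991). Basement membrane genes went 5 higher and 1 lower of 25 (6 and 1 adjusted over the list alone; camera adjusted p = 0.00837, and adjusted p = 0.439 with an estimated correlation), Col4a5 being at 193 ± 20.6 against 50.9 ± 6.28 CPM and Col4a6 at 77.6 ± 10.5 against 7.90 ± 1.77. Smooth muscle and pericyte markers went 3 higher and 0 lower of 17 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00837, and adjusted p = 0.211 with an estimated correlation), and Myl9 was at 247 ± 17.0 against 38.2 ± 8.72. Fibroblast identity genes went 4 higher and 8 lower of 25 (4 and 9 adjusted over the list alone; camera adjusted p = 0.104), with Tcf21 at 247 ± 28.1 against 54.1 ± 15.8 among the higher and Cd248 at 157 ± 17.5 against 1279 ± 320 among the lower. Mesothelial markers went 0 higher and 5 lower of 12 (0 and 10 adjusted over the list alone; camera adjusted p = 1.04e-05, and adjusted p = 0.334 with an estimated correlation), with Wt1 at 12.01 ± 2.54 against 76.2 ± 11.6. Cholangiocyte markers went 0 higher and 2 lower of 22 (0 and 4 adjusted over the list alone; camera adjusted p = 0.00278, and adjusted p = 0.439 with an estimated correlation). Ptch1 was at 105 ± 30.5 against 30.8 ± 6.55 CPM (adjusted p = 0.00591), a call that was lost without Gli3FF replicate 2 (1.44, adjusted p = 0.117).

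Of 24383 genes 509 were higher and 576 lower in Gli3FF, and DESeq2 called 908 and 1692. The count was 485 against wild type 4 and 5, 1075 against wild type 1 to 3, and 319 and 613 without Gli3FF replicate 1 or 2.

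Gli2FFGli3FF was compared with wild type to ask what loss of both factors changes. Gli2 was at 1.55, 6.39, 5.41 and 5.997 CPM in replicates 1 to 4 against 17.7 ± 3.23 in wild type, and Gli3 at 7.63, 6.39, 2.83 and 6.40 against 36.4 ± 6.31. They changed by −1.87 (SE 0.42, adjusted p = 0.00386) and −2.65 (SE 0.31, adjusted p = 4.52e-06). Gli1, whose transcription depends on the pathway, was at 0.27, 1.06, 0.43 and 2.51 CPM against 13.8 ± 7.72 and changed by −3.67 (SE 0.68, adjusted p = 0.000648). Ptch1 was at 57.5 ± 21.2 against 30.8 ± 6.55 (adjusted p = 0.0533) and Hhip at 6.70 ± 6.11 against 5.66 ± 5.54 (adjusted p = 0.834). The median over all genes was −0.353 (−0.106 over protein-coding genes outside the ribosomal proteins), against −0.327 with RLE scaling in edgeR and 0.000 with DESeq2. RLE scaling in edgeR thus did not bring it to the DESeq2 value. Whether the genes covered did so was not tested. Relative to those protein-coding genes, rises would be smaller and falls larger. Log2 changes in the rest of this comparison are relative to the −0.353. Hedgehog target genes went 1 higher and 2 lower of 13 (2 and 2 adjusted over the list alone; relative median 0.20; camera adjusted p = 0.843).

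In Gli2FFGli3FF myofibroblast and contractile genes went 10 higher and 2 lower of 22 (10 and 4 adjusted over the list alone), with a median of 0.98, camera adjusted p = 0.00449 and adjusted p = 0.445 with an estimated correlation. Myl9 rose by 2.05 (SE 0.29) and Timp1 by 2.63 (SE 0.44), and the collagen-binding integrin Itga11 fell by 2.65 (SE 0.42). Growth factors for epithelium went 6 higher and 1 lower of 30, also adjusted over the list alone (median 0.67; camera adjusted p = 0.0784), Igf1 being at 1463 ± 483 against 723 ± 61.6 CPM and Fgf10 at 110 ± 63.1 against 40.2 ± 12.2. Cytokines and chemokines went 7 higher and 3 lower of 33 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0816), with the neutrophil chemokine Cxcl5 at 201 ± 118 against 36.2 ± 6.56 and Il6 at 46.8 ± 14.0 against 3.72 ± 2.48. Wnt4 rose by 3.03 (SE 0.38) and Wnt5a fell by 0.65 (SE 0.18). Fibroblast identity genes went 0 higher and 11 lower of 25 (1 and 13 adjusted over the list alone; median −0.36; camera adjusted p = 0.00813, and adjusted p = 0.467 with an estimated correlation), with Cd248 at 137 ± 46.5 against 1279 ± 320 CPM and Pi16 at 186 ± 66.8 against 1179 ± 168. Fibrillar matrix genes went 2 higher and 14 lower of 39 (3 and 16 adjusted over the list alone; median −0.24; camera adjusted p = 0.0372, and adjusted p = 0.68 with an estimated correlation), and Loxl1 and Loxl3 fell by 1.11 (SE 0.23) and 1.81 (SE 0.30). Cell cycle genes went 7 higher and 0 lower of 44 (6 and 0 adjusted over the list alone; camera adjusted p = 0.000118, and adjusted p = 0.521 with an estimated correlation), among them the replication factor Pcna, which rose by 2.08 (SE 0.23).

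Oxidative phosphorylation genes went 24 higher and 3 lower of 38 in Gli2FFGli3FF (26 and 3 adjusted over the list alone), with a median of 1.28, camera adjusted p = 5.63e-14 and adjusted p = 0.467 with an estimated correlation. Immediate-early genes went 9 higher and 2 lower of 34 (12 and 2 adjusted over the list alone; camera adjusted p = 0.000901, and adjusted p = 0.467 with an estimated correlation). Rps2 was at 32.8 ± 4.15 against 490 ± 79.2 CPM and the nuclear noncoding RNA Malat1 at 534 ± 135 against 5948 ± 3090. These groups moved with a mitochondrial share of 11.5 to 15.7% and a ribosomal RNA share of 38.4 to 50.03%, against 13.4 to 29.4% in wild type. Xist was at 6.17 to 46.4 CPM in these libraries and Ddx3y at 0.567 to 102.6, against 37.6 to 63.1 for Ddx3y in wild type, so differences tied to sex are not separated from those of the genotype. The library with the most Ddx3y thus also held Xist reads, and the cause was not tested. Xist was under 5 CPM of total counts in 1 of 4 Gli2FFGli3FF libraries (0 of 4 by TMM-scaled CPM), so a fit of low-Xist libraries cannot separate sex from genotype here. Of 24383 genes 1853 were higher and 2330 lower. The count was 2213 against wild type 4 and 5 and 3036 against wild type 1 to 3, and between 2960 and 3619 when any single library was left out.

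Gli2FFGli3FF was also set against SmoFF, loss of the transcription factors against loss of the receptor. Gli1 was at 1.07 ± 1.02 against 12.04 ± 5.98 CPM, Gli3 at 5.81 ± 2.07 against 42.3 ± 13.9 and Smo at 44.9 ± 9.13 against 7.88 ± 0.918 (n = 4 each). The median over all genes was −0.273 (−0.173 over protein-coding genes outside the ribosomal proteins), against −0.299 with RLE scaling in edgeR and 0.000 with DESeq2. RLE scaling in edgeR thus did not bring it to the DESeq2 value. Whether the genes covered did so was not tested. Relative to those protein-coding genes, rises would be smaller and falls larger. Relative to the −0.273, Gli1 fell by 3.20 (SE 0.69), Ccn2 rose by 3.98 (SE 0.54) and Acta2 by 3.45 (SE 0.56). Hhip rose by 2.54 (SE 0.74), or 2.265 before the shift, the change that was called (adjusted p = 0.0395). The call was lost without Gli2FFGli3FF replicate 3 or 4 or SmoFF replicate 2, 3 or 4 (adjusted p from 0.0637 to 0.143). Myofibroblast and contractile genes went 7 higher and 1 lower of 22 (8 and 1 adjusted over the list alone; camera adjusted p = 0.000163, and adjusted p = 0.0876 with an estimated correlation). Oxidative phosphorylation genes went 25 higher and 1 lower of 38 (28 and 2 adjusted over the list alone; camera adjusted p = 1.48e-15, and adjusted p = 0.638 with an estimated correlation). Fibrillar matrix genes went 9 higher and 5 lower of 39 (12 and 6 adjusted over the list alone; camera adjusted p = 0.091). Of 24383 genes 1872 were higher and 2154 lower, and ribosomal RNA took 38.4 to 50.03% of counts against 10.2 to 29.6%.

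The departure of Gli2FFGli3FF from the sum of the Gli2FF and Gli3FF changes asks whether the losses add on the log2 scale. Sfrp2 was at 59.1 ± 22.5 CPM in Gli2FFGli3FF, 43.7 ± 29.4 in Gli2FF, 1.07 ± 0.221 in Gli3FF and 183 ± 49.0 in wild type, and Bmp4 at 16.7 ± 6.85, 22.3 ± 3.78, 251 ± 29.6 and 30.1 ± 4.30. Over all genes the median was −0.046 and lay 0.114 lower with RLE scaling, and relative to it the departures were 9.34 (SE 0.76) for the structured RNA Rn7s2, −6.09 (SE 1.01) for the transcription factor Zbtb16. They were 7.89 (SE 0.72) for Sfrp2, −3.43 (SE 0.44) for Bmp4, 6.55 (SE 1.04) for Dpp4, 3.59 (SE 0.68) for Pi16 and −3.34 (SE 0.56) for Col4a6. Immediate-early genes went 0 higher and 11 lower of 34 (3 and 15 adjusted over the list alone; camera adjusted p = 0.0279, and adjusted p = 0.65 with an estimated correlation), and mesothelial markers 2 higher and 0 lower of 12 (4 and 0 adjusted over the list alone; camera adjusted p = 0.00111, and adjusted p = 0.65 with an estimated correlation). TMM scaling gave 471 genes higher and 326 lower of 24383, and RLE scaling 365 and 386. Of the TMM calls 175 higher and 13 lower were pseudogenes. The wild type libraries with their pseudogene sets enter this contrast, so these calls cannot be read as an interaction of the deletions. The count was 206 with wild type 4 and 5 alone and 1332 with wild type 1 to 3, 471, 508 and 479 without wild type 1, 2 or 3, 190 and 415 without Gli2FF 1 or 2, 216 without Gli3FF 2, and 496, 479 and 484 without Gli2FFGli3FF 1, 2 or 3.

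**Figure D4:**
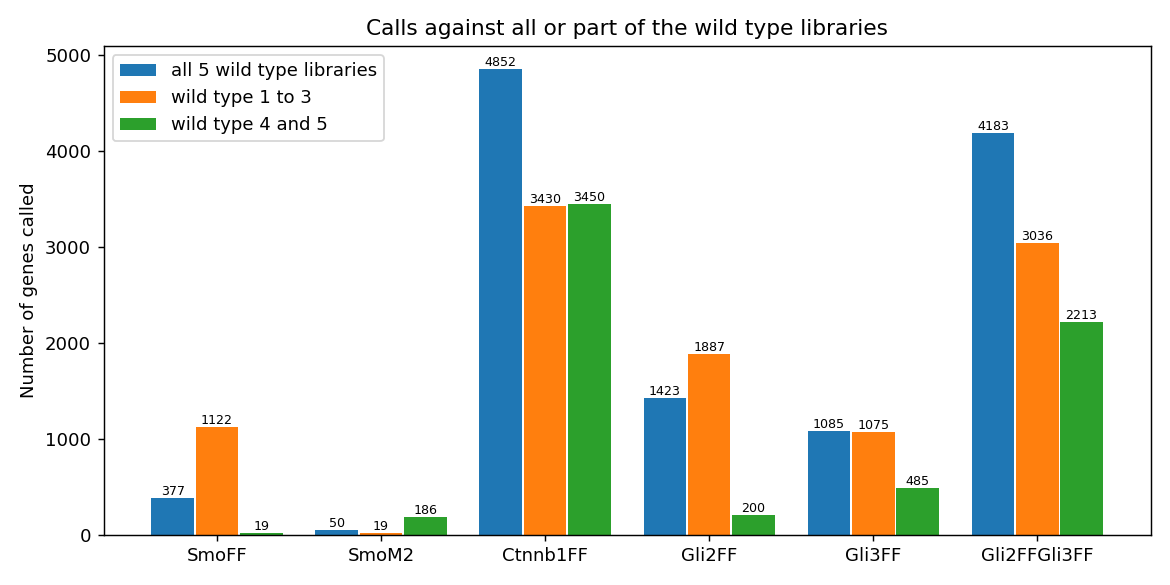
Bars give the genes called in each comparison with wild type when the controls are all 5 wild type libraries, replicates 1 to 3 or replicates 4 and 5. SmoFF has 377, 1122 and 19 called genes and SmoM2 50, 19 and 186, while Ctnnb1FF has 4852, 3430 and 3450.

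Comparisons that share the wild type libraries share their chance values, so overlaps are given beside 20 simulations of unchanged groups, all of which shared 0 calls. Unchanged groups give few calls by construction, so this 0 is no baseline for the shared counts. The values for independent lists take no account of the shared controls or of the wild type sets. SmoFF and SmoM2 shared 5 called genes, 4 higher and 1 lower in both, where independent lists would share 0.089 and 0.239. The covariance of their log2 changes across genes was 0.796 against 0.651 in the simulations (r = 0.296 against 0.399, across genes, which are not independent replicates). SmoFF and Gli2FFGli3FF shared 202 genes, 46 higher and 135 lower in both and 21 in opposite directions, where independent lists would share 5.32, 29.3 and 30.02, with covariance 1.18 against 0.649 and r = 0.268 against 0.432. SmoM2 and Gli2FFGli3FF shared 26 genes, 13 higher, 6 lower and 7 opposite (independent lists 2.36, 1.82 and 4.41), with covariance 0.617 against 0.647 and r = 0.170 against 0.391. SmoFF and Ctnnb1FF shared 136, 19 higher, 84 lower and 33 opposite (independent lists 5.63, 36.4 and 33.0), with covariance 0.846 against 0.654 and r = 0.171 against 0.392. With the wild type libraries split between the comparisons, in 20 splits, the median shared count was 1 (range 0 to 295), 44.5 (14 to 356), 6.5 (0 to 267) and 26 (11 to 467) for these pairs in the same order. In each pair the highest count came with wild type 1 to 3 as controls of 1 comparison and 4 and 5 of the other. Of the calls shared there 4, 95, 18 and 53 had the same direction, so most were opposite. Over the 20 splits the median covariance was 0.209 (range −0.681 to 0.344), 0.500 (−0.946 to 0.842), −0.0992 (−1.15 to 0.127) and 0.0568 (−1.52 to 0.575).

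The changes after ligation were set against those of the Hedgehog genotypes, which use other libraries, to ask whether the genotypes move injury genes. The lists were the called genes with the smallest p after ligation, of which 198 higher and 200 lower ones were tested in the Pdgfra libraries. In Gli2FFGli3FF, 56 of the 198 genes higher after ligation were higher and 12 lower (camera adjusted p = 4.53e-09, and adjusted p = 0.0455 with an estimated correlation), and 13 of the 200 lower after ligation were higher and 80 lower (camera adjusted p = 5.14e-06, and adjusted p = 0.219 with an estimated correlation). In SmoM2 the counts were 3 and 0 of 198 (camera adjusted p = 0.256) and 2 and 6 of 200 (camera adjusted p = 4.85e-13, and adjusted p = 0.0816 with an estimated correlation). In SmoFF they were 3 and 11 of 198 (camera adjusted p = 0.00308, and adjusted p = 0.219 with an estimated correlation) and 2 and 6 of 200 (camera adjusted p = 0.305). Across 17007 genes the log2 changes after ligation had r = 0.073 with those of Gli2FFGli3FF (rho = 0.144), 0.103 with SmoM2 (rho = 0.094) and −0.037 with SmoFF (rho = −0.038). For the 3536 genes at a mean log2 CPM of 5 or more, r was 0.302 with Gli2FFGli3FF, 0.181 with SmoM2 and −0.037 with SmoFF.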

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

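The tests of the 3 patterns were chosen only after the pattern was seen, with predictions written before each test except for the clock genes, whose rule was made stricter after the result, and the splits were raised to 100 after a smaller draw was seen. The first pattern is that oxidative phosphorylation genes were higher in Ctnnb1FF and Gli2FFGli3FF, in libraries with high ribosomal RNA shares and fewer detected genes. With a correction for GC content and transcript length, 20 of the 30 genes called higher in Ctnnb1FF stayed called higher (median log2 change, here not relative to all genes, 1.37 before and 0.59 after, SD over the list 0.856 and 0.659, medians over all genes −0.612 and −0.555) and 21 of 24 in Gli2FFGli3FF (0.93 and 0.63, SD 0.796 and 0.609, over all genes −0.353 and −0.324), which argues against that trend as the whole cause. With the ribosomal RNA share as a covariate 29 of 30 and 16 of 24 stayed called higher (medians 1.29 and 0.84, SD 0.845 and 0.768, over all genes −0.508 and −0.131), and the cause of the lost calls was not tested. The calls kept are more than the bound set before. The covariate is fitted on the spread within groups, and the shares in Gli2FFGli3FF (38.4 to 50.03%) all lie above those in wild type (13.4 to 29.4%). The covariate therefore cannot decide whether this share is the whole cause. Across the 23 Pdgfra libraries with group means removed, the list's mean had r = 0.232 with the ribosomal RNA share (permutation p = 0.491, rho = 0.334 with p = 0.262, 0.523 without the 2 libraries farthest from the median, adjusted p = 0.491 over 3 relations), so whether it follows this share within groups cannot be told apart. A difference in RNA quality between genotypes and the sex of the animals stay open, untested, beside an effect of the genotypes.

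Near-identical copies are the concern of the second pattern. The ribosomal protein genes Rps2 and Rpl34 were far lower in some genotypes, at 32.8 against 490 CPM for Rps2 in Gli2FFGli3FF and 17.8 against 149 CPM for Rpl34 in SmoFF. Their pseudogenes Rps2-ps13 (153 against 13.7 CPM) and Rpl34-ps2 (12.5 against 5.89 CPM) were higher, so a strain variant that sends reads to the copy may account for part. The summed CPM of gene and copy still changed by −1.437 log2 (SE 0.109) and −2.348 (SE 0.172), which argues against a move to these copies alone there. In Gli3FF adding the copy took Rps2 from −3.232 to −0.98 (SE 0.305) and Rpl34 from −2.191 to −1.099 (SE 0.573), and in Gli2FFGli3FF Rpl34 from −2.157 to −0.787 (SE 0.137), so part of the fall can lie in the copies there. In CPM the copies gained less than the genes lost, Rps2 in Gli3FF being at 52.2 against 490 and its copy at 203 against 13.7. Reads lost to other copies or as multiply mapped stay open, as does the genotype itself.

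Clock output genes make up the third pattern. Of 9 such genes 8 were called higher in Gli3FF and 3 each in SmoFF and Gli2FF, and all 9 were called lower in the departure from additivity. If animals were taken at different times of day, output genes should run against Arntl and Npas2, and across the 23 libraries they had r = −0.678 (permutation p = 7e-04, adjusted p = 0.0021) with rho = −0.218 (permutation p = 0.316), and r = −0.48 without the 2 libraries farthest from the median. With group means removed r was −0.557 (permutation p = 0.139, rho = −0.212). The rule asked for p under 0.05 by both Pearson's and Spearman's values, so the test does not decide. Within SmoFF, output genes were at 5.32 and 4.93 log2 CPM in replicates 1 and 2, with Arntl and Npas2 at 1.78 in both. They were at 3.71 and 2.81 in replicates 3 and 4, with Arntl and Npas2 at 4.64 and 4.97, a difference that the genotype label alone does not account for. Between genotypes, time of day and genotype cannot be told apart here. Time of day may be a candidate explanation, and the labels used here give no times.

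Other splits of the same libraries were counted for each comparison with at least 3 libraries per group. For SmoFF 7 of 100 splits drawn of 126 called at least as many genes as the real one (377), so chance cannot be excluded, and the highest other split, SmoFF 1 with wild type 1 to 3 against the rest, called 766, which follows the pseudogene sets of wild type. Against wild type 4 and 5 alone 19 genes were called, and a strain difference or a batch behind the sets stays open, since the labels name neither. The real split was alone at its count for SmoM2 (1 of 56 splits, 50 genes against 19 in the highest other), Ctnnb1FF (1 of 56, 4852 against 425, the latter wild type 1 to 3 against the rest), Gli2FFGli3FF (1 of 100 drawn of 126, 4183 against 1594), SmoM2 against SmoFF (1 of 35, 641 against 64) and Gli2FFGli3FF against SmoFF (1 of 35, 4026 against 22). Chance alone is unlikely there, by shares under 0.05 that are not adjusted over the comparisons. For SmoM2 the 50 calls fell to 17 to 36 when any 1 library was left out. Against wild type 1 to 3 they fell to 19, the count of the highest other split. For ligation 1 of 10 splits, the real one with 2326 genes, reached that count and the highest other called 0, but 10 splits are too few for a share under 0.05.

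The departure of Gli2FFGli3FF from the summed single changes was a tested difference between genotypes, with 797 genes, among them 175 pseudogenes higher and 13 lower. Single libraries stood apart from the rest of their group in 12 of 213 sets of values, and chance picks out about 1 in 20 such sets. In wild type (log2 CPM) these were Bmp4 in replicate 5, at 5.24 against 4.78 to 4.87, Ccl11 in replicate 5, at 6.93 against 7.64 to 7.86, Ccn2 in replicate 4, at 4.91 against 3.13 to 3.62, Lum in replicate 5, at 10.60 against 10.85 to 10.94, and Wnt4 in replicate 1, at 1.34 against 2.52 to 2.96. In SmoFF Col1a2 stood apart in replicate 4, at 11.11 against 10.53 to 10.59, Gli3 in replicate 2, at 4.44 against 5.59 to 5.65, Ier3 in replicate 2, at 6.97 against 6.17 to 6.25, and Rgs2 in replicate 4, at 3.002 against 4.21 to 4.37. In Gli2FFGli3FF the values were Gli2 in replicate 1, at 0.71 against 2.46 to 2.69, Loxl1 in replicate 4, at 7.75 against 8.20 to 8.27, and Malat1 in replicate 3, at 8.38 against 9.22 to 9.25.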

How the results depend on the processing

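The settings with only wild type 1 to 3 or 4 and 5, GC and length correction, ribosomal RNA share, protein-coding genes, Xist under 5 CPM and cell cycle genes left out were chosen after seeing the data. All counts below are of called genes unless said otherwise, with the main value given first, and settings not listed stayed within 1.5 times of it. The cause of these differences was not tested except where a setting removes libraries or genes. Leaving out 1 library at a time gave 377 to 2383 for ligation (2326), 121 to 685 for SmoFF (377), 17 to 36 for SmoM2 (50), 3050 to 4594 for Ctnnb1FF (4852), 179 to 1506 for Gli2FF (1423), 319 to 976 for Gli3FF (1085), 2960 to 3619 for Gli2FFGli3FF (4183), 240 to 390 for SmoM2 against SmoFF (641), 2878 to 4025 for Gli2FFGli3FF against SmoFF (4026) and 190 to 983 for the departure (797). DESeq2 called 4360 for ligation, 1302 for SmoFF, 279 for SmoM2, 2836 for Gli2FF, 2600 for Gli3FF, 1727 for SmoM2 against SmoFF and 2055 for the departure. Limma voom called 1456 for SmoM2, 5732 for Gli2FF, 1626 for SmoM2 against SmoFF and 1613 for the departure. Without a count filter the values were 1493 for ligation, 913 for SmoFF, 394 for SmoM2, 1654 for Gli3FF, 1053 for SmoM2 against SmoFF and 1920 for the departure. Fits of only the groups compared gave 151 for SmoFF, 266 for SmoM2 and 2343 for Gli2FF. Replicate numbers did not pair the libraries (mean correlation of same-numbered deviations −0.033 in Gli1, 0 of 3 pairs over 0.1, and −0.004 in Pdgfra, 4 of 55), and with the replicate block ligation had 428 calls.

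Wild type 1 to 3 as controls gave 1122 for SmoFF, 19 for SmoM2 and 1332 for the departure, and wild type 4 and 5 gave 19 for SmoFF, 186 for SmoM2, 200 for Gli2FF, 485 for Gli3FF, 2213 for Gli2FFGli3FF and 206 for the departure. With the ribosomal RNA share as covariate counts were 129 for SmoFF, 489 for Gli2FF, 2062 for Gli2FFGli3FF, 1087 for Gli2FFGli3FF against SmoFF and 181 for the departure. With GC and length correction Gli2FF had 816. Xist under 5 CPM of total counts kept 2 of 4 SmoFF, 1 of 2 Gli2FF, 1 of 2 Gli3FF and 1 of 4 Gli2FFGli3FF libraries (0 of 4 by TMM-scaled CPM), and these fewer libraries gave 128 for SmoFF, 1019 for Gli2FFGli3FF, 278 for SmoM2 against SmoFF, 697 for Gli2FFGli3FF against SmoFF and 202 for the departure. Protein-coding genes alone, fewer genes by construction, gave 161 for SmoFF, 2679 for Gli2FFGli3FF, 316 for SmoM2 against SmoFF, 2612 for Gli2FFGli3FF against SmoFF and 473 for the departure.

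Camera called 13 lists for ligation, 7 for SmoFF, 17 for SmoM2, 1 for Ctnnb1FF, 5 for Gli2FF, 10 for Gli3FF, 6 for Gli2FFGli3FF, 9 for SmoM2 against SmoFF, 3 for Gli2FFGli3FF against SmoFF and 10 for the departure. With an estimated correlation these were 0, 0, 5, 0, 0, 1, 0, 1, 0 and 0, and fry called 21 for ligation, 5 for SmoM2, 16 for Ctnnb1FF, 5 for Gli3FF and 2 for the departure. The ligation lists with an estimated correlation lost their calls in SmoM2 (lower list, adjusted p = 0.0816), SmoFF (higher list, 0.219) and Gli2FFGli3FF (lower list, 0.219), and the correlation of Gli2FFGli3FF with ligation across genes moved from 0.073 to 0.302, and that of SmoM2 from 0.103 to 0.181, at a mean log2 CPM of 5 or more. Shared calls were 80 for SmoFF with SmoM2 and 536 for SmoM2 with Gli2FFGli3FF by voom, and with split wild type 1, 44.5, 6.5 and 26 for SmoFF with SmoM2, SmoFF with Gli2FFGli3FF, SmoM2 with Gli2FFGli3FF and SmoFF with Ctnnb1FF. Ptch1 in Gli2FF against wild type (1.27) reversed without Gli2FF replicate 1, to −0.12 (adjusted p = 1), and was 1.894 without replicate 2. Of the called named genes, those kept in every setting were 33 of 43 for ligation, 7 of 25 for SmoFF, 6 of 21 for SmoM2, 28 of 35 for Ctnnb1FF, 6 of 19 for Gli2FF, 20 of 26 for Gli3FF, 20 of 36 for Gli2FFGli3FF, 9 of 11 for SmoM2 against SmoFF, 6 of 10 for Gli2FFGli3FF against SmoFF and 8 of 21 for the departure. Another join of the tables was not run, since all tables list the same genes. With 2 libraries, leaving 1 out assumes that the lone library varies like those of the other groups.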

Other observations

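The groupings by gene class in this part were made after the data were seen, and the clock genes were chosen after their values were seen. Ribosomal protein genes moved with genotype. Of 102 tested, 69 were called higher and 1 lower in Ctnnb1FF and 41 higher and 8 lower in Gli2FFGli3FF, against 1 higher and 21 lower in Gli2FF, 0 and 6 in SmoFF and 15 and 3 in Gli3FF. Their share of counts was 5.95% in Ctnnb1FF and 4.48% in Gli2FFGli3FF against 3.19% in wild type. The small structured RNAs Rn7sk and Rn7s2 were higher as well in Ctnnb1FF, at 2008 ± 639 against 34.2 ± 10.4 CPM and 763 ± 358 against 34.5 ± 4.97.

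Clock genes differed between libraries of a genotype as well as between genotypes. The mean log2 CPM of 9 clock output genes was 5.32, 4.93, 3.71 and 2.81 in SmoFF replicates 1 to 4, 6.04 and 5.62 in Gli3FF, 4.20 and 3.37 in Gli2FF, 1.99 to 2.78 in wild type and 0.82 to 1.75 in Gli2FFGli3FF. Arntl and Npas2, which peak at the opposite time of day, averaged 1.78 in both SmoFF 1 and SmoFF 2 against 4.64 and 4.97 in SmoFF 3 and 4, and −1.53 and 2.76 in Gli3FF 1 and 2 against 4.76 to 5.26 in wild type. They also lay below wild type in Gli2FF (4.54 and 4.63), where output genes were higher, in Gli2FFGli3FF (4.02 to 4.63), where output genes were lower, and in Ctnnb1FF (3.47 to 4.19), where output genes were at 1.59 to 2.68. In Gli3FF the output genes Hlf, Dbp and Per3 changed by 4.67 (SE 0.57, adjusted p = 2.71e-05), 4.99 (SE 0.99, adjusted p = 0.0036) and 3.37 (SE 0.74, adjusted p = 0.00852) by edgeR's quasi-likelihood test.

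Xist, transcribed from the inactive X, was at 14.2 to 60.7 CPM in Ctnnb1FF and 6.17 to 46.4 in Gli2FFGli3FF, and at 160 ± 194 in SmoFF, 483 ± 682 in Gli2FF and 129 ± 182 in Gli3FF (mean ± SD), where libraries with and without it occur together. It averaged 0.0446 CPM in wild type and 0.0534 in SmoM2.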
